A study of Drosophila melanogaster with 4 samples.

How the data were processed

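Chromatin from the heads of wild-type Oregon-R adult flies was immunoprecipitated with an antibody against H3K4me3 and sequenced, per the labels, in 2 ChIP replicates, each with an input sample. The labels' protocols describe homogenised tissue fixed with formaldehyde, nuclei lysed with detergent and sonication, and precipitation with antibody and protein A beads. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The authors deposited a list of enriched regions for each ChIP replicate and a list for the set of both replicates, with coordinates in FlyBase release 5, per the file headers. Each region has a start, an end and a score, and this deposited score is the authors' own value for the region. Scores were positive for enriched regions and negative for the 2 depleted regions of the combined list, which had 4981 entries in all. The region caller, its threshold, how the replicates were combined, and the scale and log base of the score are not given in the sources used here. The caller, its threshold and the way of combining can affect the number and width of regions. A region would end where enrichment meets such a threshold, but how this caller set region ends is not known. ChIP-seq regions are also wider than the mark itself, since fragments extend beyond the nucleosomes they carry.

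The 2 depleted regions were left out of all counts of enriched regions. The headers name 14 sequences, of which 13 held regions, with a total length of 168.717 Mb over the header sequences. Shares of the genome use this length, and shares of a sequence use its length in the header. Values of the replicates are given as mean and SD over 2 replicates where both are summarised. The lists hold no read counts, so the depth is unknown and no interval that needs it was computed. Exact (Clopper-Pearson) 95% intervals were given for shares of regions, and they cover counting error only.

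Regions of the replicates were called overlapping if they shared at least 1 bp. The shared bases, and in the alternatives the number of overlapping regions, were tested by shifting the regions of a list circularly along each sequence 100000 times, one-sided. For correlations and width changes, each region was paired with the region of the other replicate sharing the most bases, keeping each region in at most 1 pair. Correlations were tested by permutation, and differences in median width or score by two-sided permutation of the region labels, with 100000 resamples and a fixed seed. Counts were compared with Fisher's exact test, and comparisons of fewer than 10 regions by enumerating all arrangements. Benjamini-Hochberg adjustment was made within a family of tests where an adjusted p-value is given, and p-values printed without one are unadjusted. Regions are not independent replicates, so all tests across regions describe these lists. The sequences were grouped into the 4 large autosomal arms, chromosome 4, X, and the Het and U sequences of the assembly.

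The tests, the samples in each, the alternatives and the rule for named regions were fixed before the data were examined, except where a comparison is said to have been chosen after the data were seen. The rule named the 10 widest and the 10 highest-scored combined regions that overlapped both replicates, and the 3 widest regions of each replicate with no overlap in the other. The alternatives were a reciprocal overlap of 50%, the top 50% of regions by score, equal numbers of regions, joining of neighbours closer than 500 bp, the major arms alone, width in place of score, each replicate alone, and the combined list. Planned comparisons at transcription start sites and over gene lists were not run, because the gene table used here is of Release 6 and positions were not converted between releases. Genes and annotated features are therefore not reported.

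The overlap and width-change computations were tested on simulated data before use. Simulated lists had 4623 regions, and all regions kept in both simulated lists were found again (100%). Of 100 pairs of independently placed lists, 4% passed the p threshold of 0.05 for the overlap test. A shift of 100 bp put into X regions was recovered as 104 bp on average and passed the threshold in 100% of simulations, and without a shift 8% passed. The simulated width changes were independent normal values, and simulated regions were placed without the clustering of the real ones. These rates may therefore not carry over to the real lists. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.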

Results

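H3K4me3, the trimethylated form of lysine 4 on histone H3, is a chromatin mark found mainly at the promoters of active genes. It was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in nuclei from the heads of adult Oregon-R fruit flies, a wild-type laboratory strain of Drosophila melanogaster. The series held 4 samples, of which 2 were ChIP replicates and 2 were input chromatin. Each ChIP replicate had its own list of enriched regions, and a further list, called the combined list here, belonged to the set of both replicates. The labels name each input as the control of a replicate's list, and no separate input values were used here. The design has no second tissue, antibody or treatment, so the comparisons were between the replicates, between each replicate and the combined list, and between chromosomes. The lists give positions and a score per region but no read counts, so the sequencing depth behind each region is unknown. Nothing in the labels says that the replicates came from separate fly cultures, so part of the differences between them may be technical. The p-values come from permuting, shifting, placing or counting regions or bins of these lists. They do not measure the spread between samples. All positions are in FlyBase release 5 coordinates.

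The first comparison asked how much of the head genome carried the mark and whether the same places were found in both replicates. H3K4me3-enriched regions covered 17.7 Mb in replicate 1 and 17.8 Mb in replicate 2, in each case 10.5% of the sequences named in the file headers. Replicate 1 had 4705 regions with a median width of 3151 bp (interquartile range 2509 to 4458 bp), and replicate 2 had 4713 regions with a median width of 3148 bp (interquartile range 2500 to 4460 bp). Of the regions of replicate 1, 4581 (97.4%, exact 95% confidence interval 96.9 to 97.8%) overlapped a region of replicate 2 by at least 1 bp. In the other direction 4580 regions (97.2%, 96.7 to 97.6%) were found again. The bases covered in both lists came to 17.1 Mb, or 92.8% of the bases covered in either. When the regions of a list were shifted along their chromosomes at random, 2.57 Mb were shared on average and 25.8% of the replicate 1 regions overlapped, with a maximum of 43.5%. No shift shared as many bases as the real lists (one-sided permutation test, p = 1e-05, the smallest that 100000 shifts can give).

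The ordering of regions by strength was also shared between replicates. Among 4530 regions paired by their largest overlap, the authors' region scores had a Spearman correlation of 0.98 and a Pearson correlation of 0.98 between the replicates (permutation p = 1e-05 for each, Benjamini-Hochberg adjusted 1e-05 over 8 coefficients). Region width gave a Spearman correlation of 0.97 and a Pearson correlation of 0.96. These correlations are across regions, which are not independent replicates, and they were computed on pairs found in both lists. The score belongs to the list it stands in. Apart from these correlations and a comparison of Het regions in the closing section, it was used only within that list. There it served to describe, order, filter or compare regions, including tests of median score. In each replicate wider regions had higher scores, with a Spearman correlation of 0.71 in replicate 1 and 0.71 in replicate 2.

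**Figure D1:**
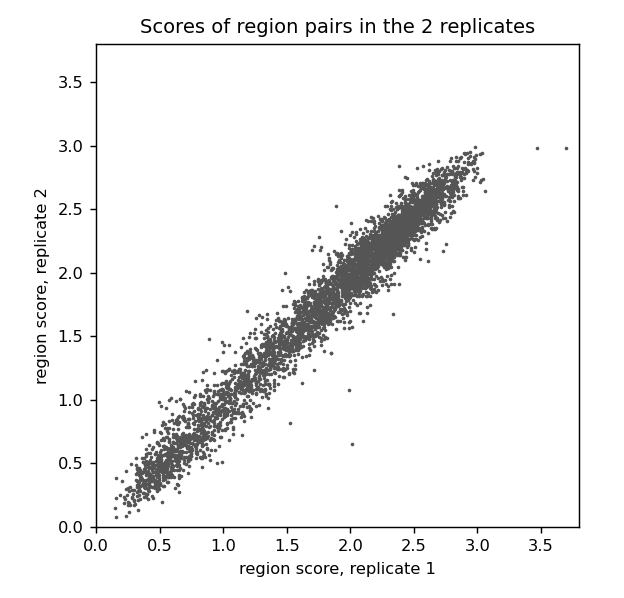
Score of each of 4530 region pairs in replicate 1 (horizontal axis, score as deposited) and in replicate 2 (vertical axis, score as deposited), with a point per pair. The points lie along a narrow diagonal band, with a Spearman correlation of 0.98.

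Regions seen in a single replicate were the narrow, low-scored ones. The 124 regions of replicate 1 with no counterpart had a median width of 1560.5 bp, against 3202 bp for the regions found again, and a median score of 0.49 against 1.95. The 133 such regions of replicate 2 had a median width of 1515 bp against 3208 bp and a median score of 0.49 against 1.91. All 4 differences passed a two-sided permutation test with p = 1e-05, the smallest possible, and an adjusted p of 1e-05. The widest of them in replicate 1 lay on X at 4320407 to 4322814 (2408 bp), on 3L at 22452164 to 22454463 (2300 bp) and on 3L at 21964914 to 21967166 (2253 bp). In replicate 2 the 3 widest were all on X, at 14993727 to 14997512 (3786 bp), 14949695 to 14952761 (3067 bp) and 1912111 to 1915130 (3020 bp). The combined list held a region at each of these 6 places.

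The combined list was set against the list of each replicate. It held 4979 enriched regions covering 19.1 Mb, or 11.3% of the header sequences, with a median width of 3171 bp. Of these, 4475 (89.9%) overlapped regions of both replicates, 119 overlapped replicate 1 only, 122 overlapped replicate 2 only and 263 overlapped neither. Regions overlapping both replicates had a median width of 3417 bp and a median score of 1.90. Those overlapping a single replicate had medians of 1656 bp and 0.32, and those overlapping neither had 1294 bp and 0.34. The narrowest region was 1001 bp wide in the combined list, 1301 bp in replicate 1 and 1302 bp in replicate 2. Among the 263 combined regions without a counterpart, 133 (50.6%) were narrower than 1301 bp, while none of the 4475 shared with both replicates were. Only 2 regions of replicate 1 and 4 of replicate 2 had no combined region. The combined list belongs to the set of both replicates and was not treated as an independent sample, so these counts were not tested.

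The broadest domains of the mark were far wider than the typical region. In the combined list 127 regions exceeded 10 kb and held 8.28% of the covered bases, compared with 93 regions and 6.32% in replicate 1 and 94 regions and 6.39% in replicate 2. The widest combined region found in both replicates lay on 3R at 11180705 to 11204313 and spanned 23609 bp, although each replicate showed 3 separate regions there. The next was on 2R at 19907342 to 19927611 (20270 bp), which was covered by 2 regions in each replicate. On 2L, the region at 10421104 to 10441133 (20030 bp) was a single region in both replicates, 19897 bp wide in replicate 1 and 19980 bp in replicate 2. A further continuous domain on 2L at 4964700 to 4984181 spanned 19482 bp, and another at 11985902 to 12003238 spanned 17337 bp. The X chromosome held 4 of the 10 widest. Of these, 3 fell close together, at 15741053 to 15758080 (17028 bp), 15772409 to 15791460 (19052 bp) and 15872871 to 15889883 (17013 bp), and the other lay at 11238436 to 11254875 (16440 bp) and was a single region in each replicate. The first of the 3 was covered by 2 regions in replicate 1 and 3 in replicate 2, and the next by 2 and 1. At 15872871 each replicate had 2 regions, the wider of them 7195 bp in replicate 1 and 8892 bp in replicate 2. The last of the 10 was on 3R at 17846405 to 17863140 (16736 bp).

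The 10 highest-scored combined regions found in both replicates were 2270 to 5935 bp wide, against a median of 3171 bp for the whole list, and lay elsewhere. The top score among them, 3.34, belonged to a 2270 bp region on U, the collection of unplaced sequence, at 7530933 to 7533202. Another region on U, at 6383837 to 6387374, came next among the regions found in both replicates, with 2.96. On 3L, 4 regions were among the 10 highest-scored found in both replicates, at 2369498 to 2375432 (2.96), 359553 to 363371 (2.93), 17505001 to 17509258 (2.91) and 19796460 to 19802366 (2.91). On 2R there were 3, at 17054138 to 17060046 (2.93), 10038059 to 10042777 (2.93) and 12081961 to 12086819 (2.92), and X held the region at 2501111 to 2505337 (2.91). None of these 10 was among the 10 widest. Whether the regions lie in genes was not analysed here, because the gene table at hand belongs to another release of the genome.

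The distribution over chromosomes showed the small chromosome 4, which is rich in heterochromatin, with the largest covered share, and the heterochromatic and unplaced sequences with shares below those of the major arms. Enriched regions covered 21.9% ± 0.354 (SD, n = 2) of chromosome 4, against 14.3% ± 0.0882 of the 4 large autosomal arms together (2L, 2R, 3L and 3R). The ratio was 1.53 ± 0.0153 (n = 2) for covered share and 1.26 ± 0.000477 for regions per Mb, both further from 1 than the spread between replicates. That spread shows how closely the 2 lists repeat each other. It leaves out the counting error of the few regions on chromosome 4, and the ratios were not tested. Chromosome 4 had 66 regions in each replicate, or 48.8 per Mb, against 38.7 ± 0.0146 per Mb on the large arms. This excess belonged to the whole list and not to its strongest part. Among the top 50% of regions by score, the chromosome 4 ratios turned to 0.968 for covered share and 0.806 for regions per Mb. Chromosome 4 regions had median widths of 3890.5 bp in replicate 1 and 3540 bp in replicate 2, which were 771 bp and 466.5 bp above those of the large arms. The width difference passed a two-sided permutation test in replicate 1 (p = 0.00291, adjusted 0.0407 over 14 tests) and not in replicate 2 (p = 0.0608, adjusted 0.142). Median scores on chromosome 4 were 1.72 in replicate 1 and 1.60 in replicate 2, against 1.92 and 1.88 on the large arms, and these differences did not pass after adjustment (adjusted permutation p = 0.240 and 0.12). The ratios of chromosome 4 to the large arms were not planned, and its tests of width and score were chosen after the data were seen.

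Among the large arms 2R was the most densely marked. It was covered to 16.3% ± 0.12 (SD, n = 2) and had 44.4 ± 0.100 regions per Mb, followed by 3R with 14.6% ± 0.0562, 3L with 13.4% ± 0.0774 and 2L with 13.2% ± 0.109. Relative to the other large autosomal arms, 2R had 1.18 ± 0.00189 times the covered share and 1.20 ± 0.00422 times the regions per Mb, ratios that were not planned. The arms closest to each other, 3L and 2L, had 36.4 ± 0.288 and 35.8 ± 0.184 regions per Mb, and even these differed by more than the SD of either. The SD covers repeat calling in 2 lists and not counting error, so it does not show that these 2 arms differ in density. In the assembled heterochromatin of the autosomes (2LHet, 2RHet, 3LHet and 3RHet) the covered share was 1.66% ± 0.0940 with 4.87 ± 0.243 regions per Mb. It was 7.25% ± 0.157 on XHet, 2.60% ± 0.158 on YHet and 0.623% ± 0.0473 on U. XHet had 4 regions in each replicate and YHet had 4 and 5, so these shares rest on few regions. All shares use the full header length, and how much of each sequence reads could be aligned to is not known. Low shares on the Het sequences and U therefore need not mean less of the mark. The regions that did occur in autosomal heterochromatin differed from those of the large arms by less than the tests could detect, with median widths of 3078 bp and 2951 bp in replicates 1 and 2 (adjusted permutation p = 0.895 and 0.774, chosen after the data were seen).

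**Figure D2:**
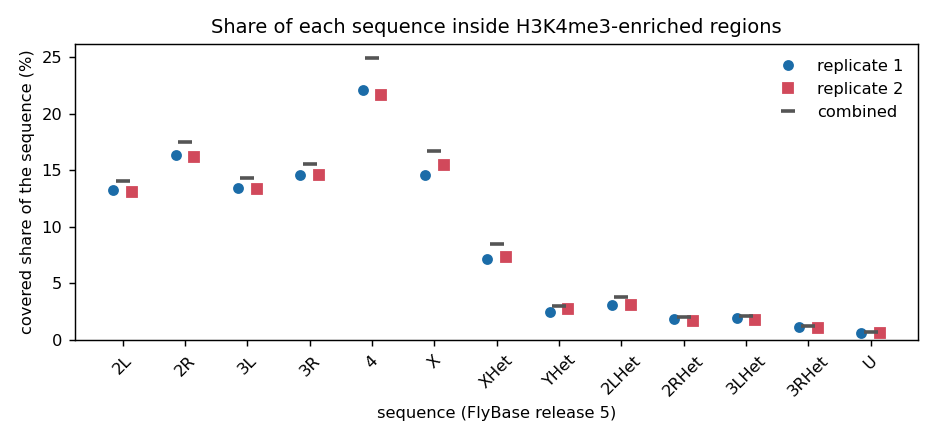
Covered share (vertical axis, percent of the sequence length) of each sequence of the FlyBase release 5 assembly (horizontal axis), with circles for replicate 1, squares for replicate 2 and dashes for the combined list. Chromosome 4 stands highest at 21.9% on average over the replicates, and the Het sequences and U lie below the 6 major arms.

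The X chromosome carried wider regions than the 4 large autosomal arms together. Its covered share was 15.0% ± 0.623 (SD, n = 2), 1.05 ± 0.050 times that of the large autosomal arms, a difference no larger than the spread between replicates. The ratio was 1.01 in replicate 1, 1.08 in replicate 2, 1.09 in the combined list and 1.12 among the top 50% of regions by score. The last 3 lay further above 1 than that spread. All rest on the same 2 replicates, and replicate 2 helps to set the spread, so they are not separate evidence of an excess. X had 0.951 ± 0.00942 times as many regions per Mb as those arms together, a ratio that rose to 1.00 (0.999922) among the top 50% of regions by score. With 36.8 ± 0.378 regions per Mb, X lay above 2L and 3L and below 2R and 3R in each replicate. The median X region was 3331 bp wide in replicate 1, 211.5 bp wider than on the large autosomal arms (two-sided permutation p = 0.00484, adjusted 0.00484). In replicate 2 it was 3427 bp wide, 353.5 bp wider (permutation p = 3e-05, adjusted 9e-05), and in the combined list 3467 bp, 337.5 bp wider (p = 9e-05, adjusted 0.000135). The large autosomal arms also differed among themselves, with medians from 2959 bp on 2L to 3239 bp on 3R in replicate 1. In replicate 2 their medians ranged from 2960 bp on 2L to 3233.5 bp on 3R. The permutation pooled these arms and so left out the variation among them. Regions over 10 kb made up 25 of 819 (3.05%) on X and 64 of 3738 (1.71%) on the large autosomal arms in replicate 1 (Fisher's exact p = 0.0171, adjusted 0.0171). The counts in replicate 2 were 28 of 831 (3.37%) and 64 of 3740 (1.71%), with an exact p of 0.00378 and an adjusted p of 0.00568. The comparison above 10 kb was chosen after the data were seen. In replicate 1 it did not hold for the top 50% of regions by score (exact p = 0.0861) or after neighbours closer than 500 bp were joined (exact p = 0.0806). Median X scores were 1.97 and 1.93 in replicates 1 and 2, 0.05 above those of the large autosomal arms (differences not past the threshold, adjusted permutation p = 0.382 and 0.343, chosen after the data were seen).

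X regions tended to be wider in replicate 2, and those of chromosome 4 narrower. The covered share of X was 14.6% in replicate 1 and 15.5% in replicate 2, while every other major arm was covered slightly less in replicate 2. Of 769 X region pairs, 526 (68.4%, exact 95% interval 65.0 to 71.7%) were wider in replicate 2, against 1576 of 3624 (43.5%, 41.9 to 45.1%) on the large autosomal arms. The median width change from replicate 1 to replicate 2 was 91 bp on X and -17 bp on the other 5 major arms, a difference of 108 bp (two-sided permutation p = 1e-05, the smallest possible). Mean changes in bins of 1 Mb gave a larger difference of 269 bp, with 232 bp on X and -36.6 bp on the other arms (permutation p = 1e-05). Chromosome 4 moved the other way, with 18 of 62 pairs wider in replicate 2 (29.0%, 18.2 to 41.9%) and a median change of -77.5 bp, against -16 bp on the large autosomal arms (permutation p = 0.00092, adjusted 0.00184 over 2 tests). The autosomal Het sequences, with 10 of 41 pairs wider (24.4%, 12.4 to 40.3%) and a median change of -50 bp, did not pass the same test (permutation p = 0.114, adjusted 0.114). Without chromosome 4 among the other arms, the X difference was 107 bp. On X, 57 pairs were over 1000 bp wider in replicate 2 and 12 were over 1000 bp narrower, compared with 37 and 61 on the large autosomal arms. X regions made up 52 of the 133 regions found in replicate 2 alone (39.1%, 30.8 to 47.9%) and 26 of the 124 found in replicate 1 alone (21.0%, 14.2 to 29.2%), a difference with a Fisher's exact p of 0.00178. Of all regions, 17.4% in replicate 1 and 17.6% in replicate 2 lay on X. These comparisons of widths and single-replicate regions by chromosome were chosen after the data were seen.

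**Figure D3:**
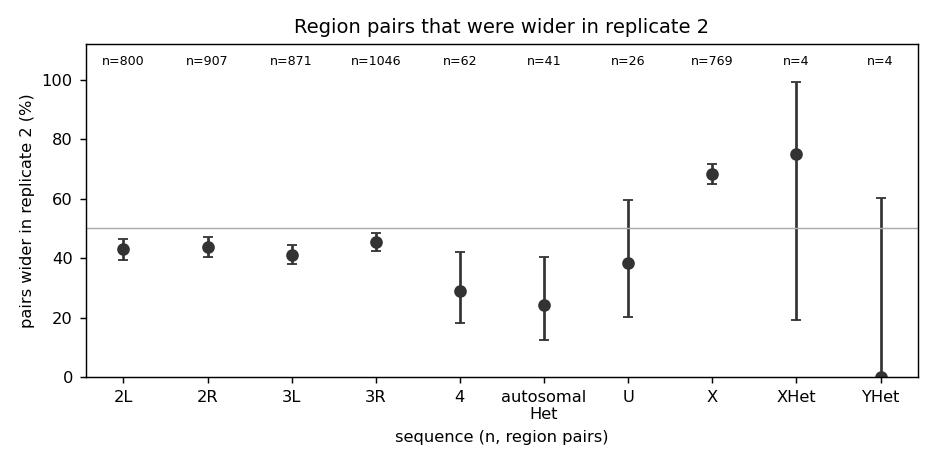
Share of region pairs that were wider in replicate 2 than in replicate 1 (vertical axis, percent) for each sequence (horizontal axis), with bars for exact 95% confidence intervals, n for the number of pairs and a line at 50%. The share on X is 68.4%, while the 4 large autosomal arms lie between 41.2% and 45.5%.

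Along the arms the mark was unevenly spread, and the replicates followed each other closely. In 242 bins of up to 500 kb the mean covered share of the replicates ranged from 1.42% to 36.8%, with a median of 13.8%. The most densely marked bins were on 2R at 19500001 to 20000000 (37.0% in replicate 1 and 36.6% in replicate 2), on X at 15500001 to 16000000 (35.4% and 37.1%) and on 2L at 10000001 to 10500000 (35.7% and 35.1%). Each of these held at least 1 of the 10 widest domains. The sparsest full bins were on 3L at 23500001 to 24000000 (1.45% and 1.38%), on 2L at 14500001 to 15000000 (1.67% and 1.69%) and on 3L at 24000001 to 24500000 (2.09% and 1.81%). The last 1 Mb of each arm toward the centromere was less covered than the rest on 4 arms. It was covered to 2.36% ± 0.131 (SD, n = 2) on 3L against 13.9% ± 0.0751 for the rest, 6.68% ± 0.0825 against 13.5% ± 0.118 on 2L, 7.03% ± 0.0115 against 16.8% ± 0.125 on 2R and 6.63% ± 0.337 against 15.4% ± 0.637 on X. On 3R the values were 15.3% ± 0.0776 and 14.6% ± 0.0554, with the higher one near the centromere. The bins and the centromeric comparison were chosen after the data were seen and were not tested. How much of each stretch reads could be aligned to is not known, so a low share there need not mean less of the mark.

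**Figure D4:**
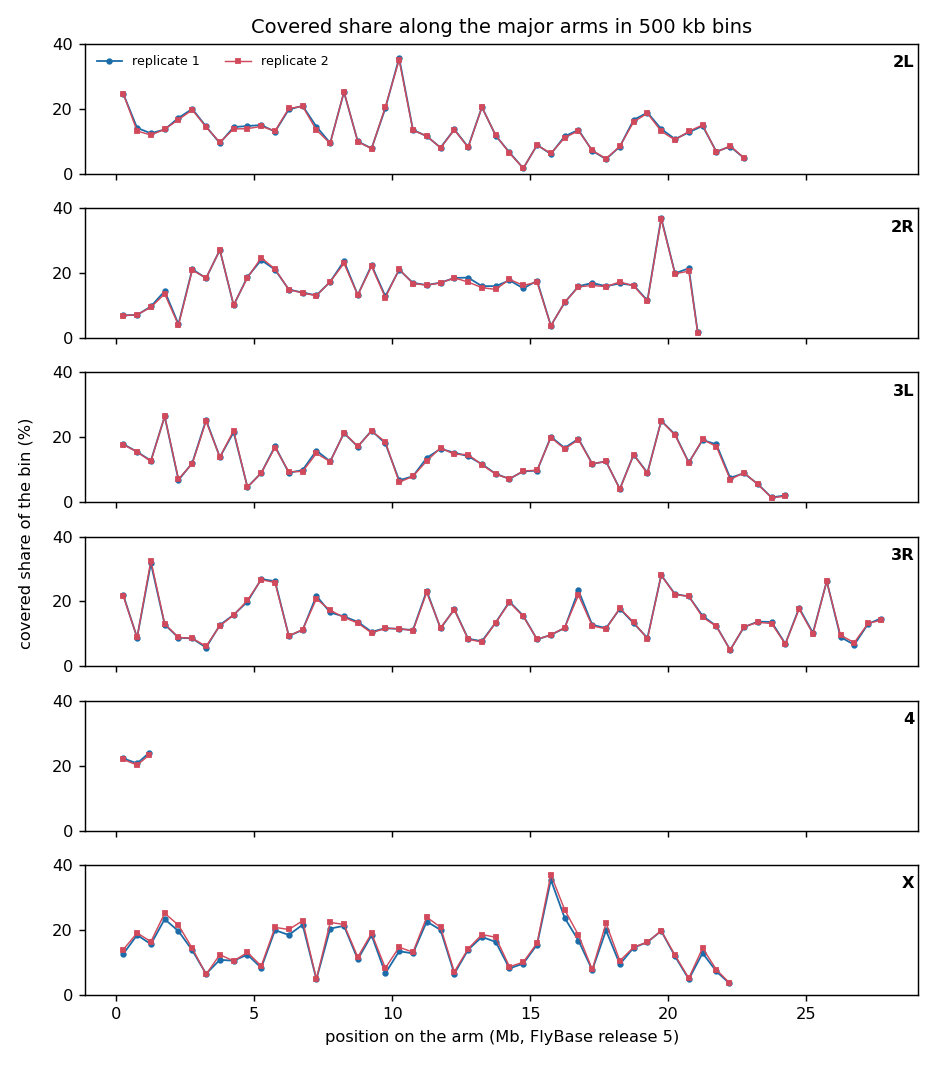
Covered share (vertical axis, percent of each bin of up to 500 kb) along the 6 major arms (horizontal axis, position in Mb, FlyBase release 5), with circles for replicate 1 and squares for replicate 2. The peaks on 2L, 2R and X reach over 35% in both replicates, and the lines of the replicates nearly coincide except on X, where replicate 2 often lies higher.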

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

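The alternatives for the width change of X regions between replicates were chosen after the data were seen. So was the use of chromosome 4 or X as part of the reference arms. The other settings were planned. Ratios to the autosomal arms were planned for X only, so those of chromosome 4 and 2R were unplanned in every setting. Of 78 alternatives for 20 results, 60 left the value within the spread between replicates, on the same side of the test or, for counts, within 1.5 times the count. For the chromosome ratios, leaving out a replicate could not move the value beyond the spread, which is the SD of those same 2 replicates. Those alternatives therefore count among the 60 by construction. All 38 with a test kept their direction and stayed past the threshold, covering the overlap, the correlations, the regions found in a single replicate, the width of X regions and their change between replicates. Taking the top 50% of regions by score reversed the chromosome 4 ratios to 0.968 for covered share and 0.806 for regions per Mb, and the cause was not tested. In the same setting the X covered share rose beyond the spread, and ratios were 1.12 (covered share) and 1.00 (regions per Mb, 0.999922) for X, and 1.17 and 1.18 for 2R. For the combined list it left 2484 regions overlapping both replicates, 0 overlapping 1 and 6 overlapping neither. The share overlapping both was 99.8%, against 89.9% in the whole list. This setting keeps fewer regions by construction and drops low-scored ones. Regions overlapping 1 or neither replicate had low median scores in the whole list (0.32 and 0.34). With the combined list in place of the replicates, the X covered share ratio was 1.09, regions per Mb on X came to 0.977, the chromosome 4 ratios to 1.63 and 1.35, and the 2R ratios to 1.19 and 1.22. Joining neighbours gave regions per Mb ratios of 0.939 for X, 1.27 for chromosome 4 and 1.22 for 2R. Adding X to the reference arms gave 1.27 for chromosome 4. For the other shifts too the cause was not tested, and the SD over 2 replicates they were judged by is itself uncertain. Leaving out a replicate gave X ratios of 1.01 to 1.08 and 0.944 to 0.957, chromosome 4 ratios of 1.52 to 1.54 and 1.26 in both cases, and 2R ratios of 1.18 in both cases and 1.19 to 1.20. No paired analysis was possible because the inputs have no region lists of their own to pair with the ChIP replicates. The settings planned for transcription start sites and gene lists were not run. Depth is unknown, so weak regions found in a single list cannot be separated into absent and undetected ones.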

Other observations

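All tests and regions of this part were chosen after the results were seen. H3K4me3 regions clustered along the arms and left long stretches free. Across the 6 major arms, 24 stretches of over 200 kb held no enriched region in any of the 3 lists, with 7 on X, 6 on 2L, 5 on 3L, 3 on 2R, 3 on 3R and 0 on chromosome 4. The longest lay on 3R at 2486719 to 2891179 (404 kb), followed by 3L at 23334941 to 23707181 (372 kb), X at 21502078 to 21844766 (343 kb), 3R at 12481507 to 12811505 (330.0 kb) and 3L at 24225808 to 24529521 (304 kb). Both of the long stretches on 3R lie inside the arm, outside the 1 Mb next to the centromere, while those on 3L lie near its centromeric end. Taken alone, replicate 1 had 29 such stretches and replicate 2 had 32, whereas placing the same regions at random on each arm gave 0.716 and 0.688 on average and at most 4 and 5 (permutation p = 0.000999 for each, the smallest that 1000 placements allow). At the other end, 310 neighbouring pairs in replicate 1 and 323 in replicate 2 lay less than 500 bp apart, against 103 and 104 on average with random placement (permutation p = 0.000999 for each). Random placement ignores genes and sequence gaps in the assembly, so it is a low bar.

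The wider X regions of replicate 2 were weighed against 3 explanations, and the design names no biological difference between the replicates that was tested. A change of weak regions alone is argued against, since among the 25% of pairs with the highest score in replicate 1 the X difference was 159 bp (142 bp on 204 X pairs and -17 bp on 910 others, permutation p = 1e-05), but enrichment that meets the caller's threshold further out along the whole X would move strong regions too and stays open. A few local stretches are also argued against, since 22 of 23 bins of 1 Mb on X had a positive mean width change (one-sided exact binomial p = 0.0116 against a share of 0.75), compared with 33 of 100 on the other arms. The share of 0.75 was set after the results were seen, and bins of 1 chromosome are not independent. The counts, and not this p-value, therefore carry the argument. Over X pairs the mean change was 233 bp and the median 91 bp, so a few large changes can set the mean of a bin. The counts thus do not show that most regions within each bin were wider. A different make-up of male and female chromatin in the replicates may shift X and Y in opposite directions, and it stays open: relative to the autosomal Het regions the median width change was -110 bp for 4 YHet pairs (exact p = 0.337) and 133.5 bp for 4 XHet pairs (exact p = 0.268). Scores of the YHet and XHet pairs went the same way. They were lower in replicate 2 in 4 of 4 YHet pairs (medians 1.69 and 1.01) and 32 of 41 autosomal Het pairs. They were higher in 4 of 4 XHet pairs (2.17 and 2.24). Mean differences from the autosomal Het pairs were -0.46 for YHet (exact p = 6.71e-05) and 0.22 for XHet (exact p = 0.00043). However, the score's scale is not given, and scores of separate lists may not be comparable. On the X arm the median score lay above that of the large autosomal arms by 0.0484 in replicate 1 and 0.0478 in replicate 2. This difference did not grow from replicate 1 to replicate 2.

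A 1008 bp region of the combined list on X at 4820203 to 4821210 had a score of 3.12 but overlapped no region of either replicate, and the next highest score among such regions was 2.98. The 1008 bp region was narrower than any region of the replicate lists, where the narrowest was 1301 bp. Its absence from those lists need not mean a missing signal. The 2 depleted regions of the combined list lay on 2L at 11056298 to 11057749 (1452 bp, score -0.04) and at 16847593 to 16849161 (1569 bp, score -0.02).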
